A study of Mus musculus with 6 samples.

How the data were processed

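Endothelial cells were sorted from whole mouse embryos at embryonic day 12.5, and RNA was extracted, amplified with the SMART-seq v4 kit for small inputs and made into libraries with the Nextera XT kit, per the labels' protocols. The kit does not mark strand, and whether counting used strand is not given in the sources used here, so reads of a gene and of an overlapping antisense gene cannot be told apart. Amplified cDNA without molecular identifiers counts reads rather than molecules, so a floor in counts covers counting error only. SDs, and SEs of single genes, also hold the variation between libraries. The submitters' processing notes name Trimmomatic 0.36.4, STAR 2.5.2b, Picard 2.7.1.1, featureCounts 1.4.6, DESeq2 and the mm10 genome build, with no role or order. The authors deposited 1 table of 23420 gene symbols. Its count values are as deposited by the authors, whole-number read counts per gene and library without normalization, made with the tools above per the submitters' processing notes. The deposited table also holds the authors' log2 fold change and p-value for each gene, in the direction tdTom- over tdTom+, which was turned round here. Normalized columns in the table were not used.

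Groups were taken from the sample titles, with 3 tdTom+ and 3 tdTom- libraries. Library totals were 11501313, 11010850 and 10675472 counts in tdTom+ and 10293032, 11767956 and 8919887 counts in tdTom- replicates 1 to 3, so that a floor of 3 counts was 0.255 to 0.336 CPM. No pair of libraries of one group agreed within sampling noise, with a mean chi-square per gene of 8.18 to 19.7, so all were kept as separate samples. The protocol says that the cells of 3 embryos were divided into both fractions, but the labels do not say that a number names an embryo. Deviations from the group means correlated across genes at r = 0.10, 0.087 and 0.16 for the same-numbered libraries 1, 2 and 3, and every other pairing but 1 was below 0. Deviations sum to 0 within a group, so values below 0 for the other pairings follow largely from the same-numbered ones and add little. Xist was at 1224 and 571 counts in both libraries numbered 3 and at most 8 in the others, while Ddx3y was at most 12 in those numbered 3 and at least 1204 in the others. Libraries numbered 3 thus came from female cells in both groups, and sex does not tell numbers 1 and 2 apart. The replicate number was treated as pairing the libraries on the protocol and on these values, a choice made after the numbers of calls with and without the block had been seen. The main fit and every alternative other than the replicate block, including those that leave out a library, do not use this pairing. The blocked result is given where it changed a call or moved a count by over 1.5 times.

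Genes were tested with edgeR 4.0.16 in R 4.3.3 (TMM normalization, filterByExpr with a minimum count of 10, robust quasi-likelihood fit, two-sided F-test without a block), with Benjamini-Hochberg adjustment over 13142 genes and a threshold of 0.05. Of the genes in the table, 5554 had no count in any library. Fold changes are tdTom+ minus tdTom- on the log2 scale, and their SE is the log2 fold change divided by the square root of F. The SE of a list median comes instead from the spread of its members' fold changes, with genes taken as independent. It does not measure variation between libraries. CPM values use TMM-scaled library sizes. The common biological coefficient of variation was 23.2%. On simulated data with the libraries' own means and sizes, in 12835 genes, the test recovered 30%, 64%, 80% and 84% of genes changed 1.5, 2, 4 and 8-fold, 50 of each, and 5.84% of its calls were false. In a simulation of 20 lists, camera called the 1 changed list, raised 1.5-fold, and 1 of the unchanged lists. The simulated genes varied independently, while members of a real list can vary together, at an estimated correlation of 0.45 for the interferon response list. The simulation therefore does not give the rate of false list calls in these data.

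The test, the alternatives, the gene lists and the rule for naming genes were set before the data were examined. That rule took the sort and lineage genes Csf1r, Pecam1, Ptprc, Itgam and Kit, the 8 largest changes in each direction among genes that passed, with a mean log2 CPM of at least 3 and non-overlapping groups, and up to 4 members of each list with the smallest p. Genes named outside it are said to be chosen after their values were seen. There were 24 gene lists: endothelial core, liver sinusoidal, arterial, venous, lymphatic and brain endothelium, endocardium, tip and sprouting endothelium, Hoxa cluster, the Hoxb, Hoxc and Hoxd clusters, macrophage and myeloid, haematopoietic progenitor, erythroid, megakaryocyte and platelet, hepatoblast and hepatocyte, mesenchyme and mural, neural, cell cycle, lysosome, dissociation and stress response, interferon response, glycolysis, mitochondrially encoded, and extracellular matrix of vessels. The mitochondrially encoded list had 0 members in the table used here, so 23 lists were tested. Older symbols in the table were matched to the lists' current ones, and 19 of 21 erythroid genes were in the table. Lists were tested against all other genes with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists. With an estimated correlation 5 calls held (liver sinusoidal, lymphatic, megakaryocyte and platelet, brain and arterial), and 7 lists were called by fry, which asks whether a list's genes move one way and does not compare them with other genes.

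Alternatives were DESeq2 size factors, library size only, no low-count filter, a filter of 5 CPM in at least 3 libraries, DESeq2 1.42.0, limma-voom, the replicate block, leaving out each library, removal of the genes of 4 other cell types (erythroid, macrophage, megakaryocyte and hepatoblast lists) before normalization, camera with an estimated correlation and fry. Removing germ cell genes and leaving out list members shared between lists were added after the data were seen. Gene coordinates are those of RefSeq on GRCm38, the assembly of mm10, 1-based. Nothing in the labels says whether the 3 embryos shared a litter, and no sorting or sequencing batch is given. An exact permutation test of 3 against 3 cannot go below a p of 0.1, so single genes were tested only in models fitted across all genes. Figures were drawn with matplotlib 3.10.9.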

Results

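RNA was sequenced from endothelial cells of mouse embryos at embryonic day 12.5 that carried Csf1r-iCre, a Cre recombinase driven by the Csf1r promoter, and a Rosa26 reporter that switches on the red protein tdTomato after recombination. Csf1r encodes the receptor for colony-stimulating factor 1 and is a myeloid gene, so that tdTomato marks cells that expressed it or descend from cells that did. Cells carrying the endothelial protein PECAM1, and lacking the blood cell proteins CD45, CD11b and KIT, were sorted from whole embryos into a tdTom+ and a tdTom- fraction. Each group held 3 libraries, numbered 1 to 3. The total count per library ran from 8919887 to 11767956, and 13142 of the 23420 genes in the table were abundant enough to test. Fewer genes had at least 1 count in the tdTom+ libraries, with 14432 to 15300, than in the tdTom- libraries, with 15850 to 16109.

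The comparison asked whether endothelial cells with a history of Csf1r-iCre activity have a different transcriptome from the other endothelial cells of the same embryos. Csf1r itself (chromosome 18, 61105572 to 61131139, mm10) was weakly expressed in both fractions, at 57 to 81 counts in the tdTom+ libraries and 39 to 52 in the tdTom- libraries. Its CPM was 6.16 ± 1.24 (SD, n = 3) against 4.25 ± 0.236 (SD, n = 3), and the log2 fold change of 0.54 ± 0.39 (SE) did not pass (edgeR adjusted p = 0.719). Pecam1, the sorting marker, had 831 ± 57.4 CPM in tdTom+ and 930 ± 36.3 CPM in tdTom- cells (SD, n = 3), a log2 fold change of -0.16 ± 0.07 (SE) that did not pass (edgeR adjusted p = 0.413). Kit, encoding one of the proteins gated against, had 86.7 ± 5.99 CPM in tdTom+ and 119 ± 6.10 CPM in tdTom- cells (SD, n = 3). Its log2 fold change of -0.46 ± 0.10 (SE) missed the threshold (edgeR adjusted p = 0.0581). Without the low-count filter, with the stricter filter and with DESeq2, the Kit difference passed (adjusted p = 0.0459, 0.0458 and 0.00323). Ptprc, which encodes CD45, had at most 4 counts in a tdTom+ library and at most 22 in a tdTom- library, and Itgam, which encodes CD11b, had at most 6 and 12. These were too few to test. Gt(ROSA)26Sor, the non-coding transcript of the locus that holds the reporter (chromosome 6, 113067428 to 113077244), had 63 to 132 counts in tdTom+ and 9 to 11 in tdTom- libraries. It was singled out after its values were seen. The log2 fold change was 3.23 ± 0.49 (SE, edgeR adjusted p = 0.00862), and the call ended without tdTom+ replicate 1 (adjusted p = 0.0517), tdTom- replicate 2 (0.0611) or tdTom- replicate 3 (0.0657), and with limma-voom (0.0718).

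The tdTom+ fraction held more of the transcripts of liver sinusoidal vessels and of megakaryocytes, the cells that shed platelets, and less of the transcripts of brain and arterial endothelium, of elastin and of some germ cell genes. In all, 101 genes were higher and 107 were lower in tdTom+ cells, 1.58% of those tested (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). A change of at least 2-fold was seen in 62 of the higher and 72 of the lower genes. The groups did not overlap in 17.2% of all tested genes, where chance alone gives 10% for 3 libraries against 3. An unadjusted p under 0.05 was reached by 1405 genes. With the replicate number as a block, 128 genes were higher and 167 lower, and 194 of the 208 genes kept their call. The authors' deposited table lists 211 genes as higher and 291 as lower at the same threshold, including all 101 and all 107, and DESeq2 gave 217 and 267 here. The counts fell to 61 higher and 65 lower without tdTom+ replicate 1, to 51 and 32 without tdTom- replicate 1, to 43 and 28 without tdTom- replicate 2, and to 37 and 25 without tdTom- replicate 3.

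**Figure D1:**
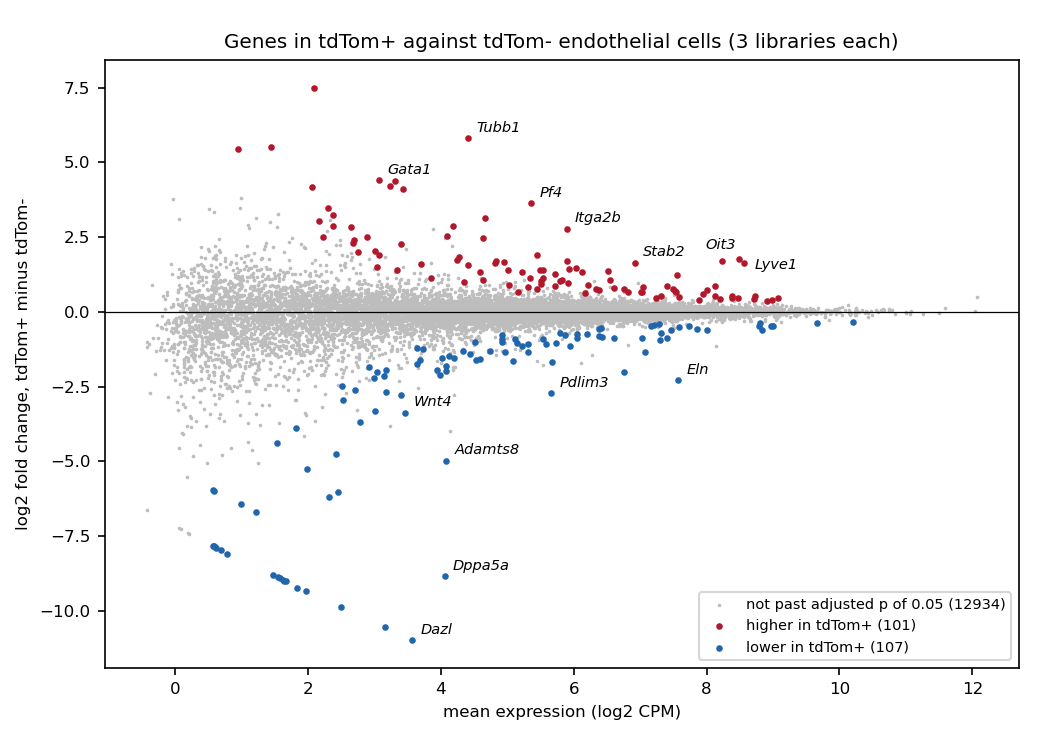
Log2 fold change of each tested gene (tdTom+ minus tdTom-, vertical axis) against its mean expression in log2 CPM (horizontal axis), 3 libraries per group. Red points are the 101 genes higher in tdTom+, blue points the 107 lower and grey points the genes that did not pass, and the positions of genes with 0 counts in all tdTom+ libraries, such as Dazl, depend on the fit's prior count.

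Among the most increased genes were several of the platelet lineage. Tubb1, the platelet beta-tubulin (chromosome 2, 174450595 to 174458380), rose from 0.690 ± 0.601 to 41.3 ± 17.2 CPM (SD, n = 3), a log2 fold change of 5.81 ± 0.58 (SE, edgeR adjusted p = 0.000766). Gata1, an erythroid and megakaryocyte transcription factor, rose by 4.40 ± 0.47 and Gp5, a platelet glycoprotein, by 4.21 ± 0.53 on the log2 scale (SE, edgeR adjusted p = 0.00128 and 0.00348). Pf4, platelet factor 4, rose from 6.05 ± 2.17 to 75.5 ± 33.5 CPM (SD, n = 3), and the integrin subunit gene Itgb3 rose by 3.13 ± 0.32 on the log2 scale (SE, edgeR adjusted p = 0.00094). The adaptor gene Sla, the membrane-curvature gene Bin2 and the alpha-tubulin gene Tuba4a were also among the 8 largest rises, with log2 fold changes of 4.37, 4.12 and 2.88. With limma-voom the calls of Tubb1, Sla, Gp5, Pf4 and Tuba4a ended (adjusted p = 0.113, 0.156, 0.0518, 0.066 and 0.0834). The call of Bin2 ended without tdTom- replicate 3 (adjusted p = 0.0877), and that of Tuba4a without tdTom- replicate 1 (0.0605), 2 (0.0661) or 3 (0.0661).

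The most decreased genes included germ cell genes with no count in any tdTom+ library. Dazl, a germ cell RNA-binding protein gene (chromosome 17, 50279393 to 50293620), had 717 counts over the tdTom- libraries and 0 over the tdTom+ libraries, and was at least 254-fold lower against a floor of 3 counts over the group. Dppa3 had 545 and 0 counts and was at least 193-fold lower, and Dppa5a had 32.9 ± 9.90 CPM in tdTom- and 0.0610 ± 0.106 CPM in tdTom+ cells (SD, n = 3). Dppa5a has near-identical copies, so its counts are uncertain. In all, 17 of the 107 lower genes had 0 counts in all tdTom+ libraries. Other large decreases were in Adamts8, a secreted metalloprotease gene, with a log2 fold change of -4.97 ± 0.65, in Pdlim3, a cytoskeletal adaptor gene, with -2.73 ± 0.23, and in the X-linked homeobox gene Rhox5 with -2.78 ± 0.40 (SE, edgeR adjusted p = 0.00435, 0.000331 and 0.0072). The signalling ligand genes Wnt4 and Wnt9b had log2 fold changes of -3.37 ± 0.59 and -3.33 ± 0.69 (SE, edgeR adjusted p = 0.0192 and 0.0403). The call of Wnt9b ended when any of the 6 libraries was left out (adjusted p from 0.0598 to 0.287) and with limma-voom (0.165), that of Wnt4 without tdTom- replicate 1 (0.11), 2 (0.0705) or 3 (0.0766), that of Rhox5 without tdTom- replicate 3 (0.0726), and that of Adamts8 with limma-voom (0.137).

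Genes of liver sinusoidal endothelium, the scavenging endothelium of the liver, formed the largest group of rises. Of the 24 measured members of this list, 15 rose, 0 fell and 9 did not pass; adjusted over the list alone, 16 rose and 3 fell. Lyve1, a hyaluronan receptor gene (chromosome 7, 110850607 to 110862953), rose from 183 ± 17.5 to 572 ± 40.8 CPM (SD, n = 3), or 3.12-fold (edgeR adjusted p = 2.66e-05). Oit3 rose 3.41-fold, the endocytosis gene Ehd3 3.26-fold and the receptor gene Gpr182 2.33-fold, with log2 fold changes of 1.77 ± 0.12, 1.70 ± 0.13 and 1.22 ± 0.11 (SE, edgeR adjusted p = 7.88e-05, 0.000243 and 0.000377). The scavenger receptor gene Stab2, which lies outside the rule for naming genes and was chosen after its values were seen, rose from 58.4 ± 7.37 to 183 ± 34.3 CPM (SD, n = 3). The list median was 0.79 on the log2 scale, and the set test called the list higher (limma's camera adjusted p = 1.07e-45 with the preset correlation, and adjusted p = 0.00528 with an estimated correlation). Alongside this, the hepatoblast and hepatocyte list had a median of -1.002, and the macrophage and myeloid list one of 0.36.

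The lymphatic endothelial list was also called higher, through few members, while the call of the venous list was lost in several alternatives. Lyve1 and Flt4, a vascular endothelial growth factor receptor gene, rose among the 9 measured lymphatic genes, and both are also members of the liver sinusoidal list. Adjusted over the list alone, 5 rose and 1 fell. Flt4 had a log2 fold change of 0.42 ± 0.07 (SE, edgeR adjusted p = 0.0191), and its call ended when any of 5 libraries was left out, all but tdTom+ replicate 3 (adjusted p from 0.058 to 0.106). The lymphatic list had a median of 0.42 (limma's camera adjusted p = 3.4e-11, and adjusted p = 0.0232 with an estimated correlation). Of 10 venous genes 1 rose, both over all genes and adjusted over the list alone. It was Nrp2, a semaphorin and growth factor co-receptor gene, with a log2 fold change of 0.53 ± 0.10 (SE, edgeR adjusted p = 0.0258), which no longer passed without tdTom+ replicate 2 or 3 or tdTom- replicate 1 or 3 (adjusted p from 0.0504 to 0.149). The venous list had a median of 0.14 and a mean of -0.03, which differ in sign, and was called higher (camera adjusted p = 0.0235, and adjusted p = 0.18 with an estimated correlation). It lost its call without tdTom+ replicate 2 (adjusted p = 0.106) or tdTom- replicate 1 (0.064), and with members shared between lists left out (0.105).

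Brain endothelial genes were lower in tdTom+ cells. Of 23 measured members 7 fell, 0 rose and 16 did not pass; adjusted over the list alone, 16 fell. Lsr, a gene of tricellular junctions, fell from 84.5 ± 3.05 to 38.3 ± 4.71 CPM (SD, n = 3), a log2 fold change of -1.14 ± 0.13 (SE, edgeR adjusted p = 0.00187). The lipid transporter gene Mfsd2a had a log2 fold change of -1.14 ± 0.22, the glucose transporter gene Slc2a1 -0.38 ± 0.07 and the amino acid transporter gene Slc7a5 -0.61 ± 0.11 (SE, edgeR adjusted p = 0.0285, 0.0191 and 0.0267). The list median was -0.60 (limma's camera adjusted p = 2.35e-18, and adjusted p = 0.0304 with an estimated correlation). The call of Mfsd2a ended without any of 5 libraries, all but tdTom+ replicate 2 (adjusted p from 0.0675 to 0.152), that of Slc2a1 without tdTom+ replicate 1 or tdTom- replicate 2 or 3 (0.0673 to 0.0949), and that of Slc7a5 without replicate 1 or 3 of either group (0.0675 to 0.15).

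Arterial genes were lower too. Jag1, a Notch ligand gene, fell with a log2 fold change of -1.03 ± 0.13 (SE, edgeR adjusted p = 0.00435). The gap junction gene Gja4 had a log2 fold change of -0.70 ± 0.13 (SE, edgeR adjusted p = 0.0258), with its call lost without tdTom+ replicate 1 or any tdTom- replicate (adjusted p from 0.0668 to 0.124). These were the 2 members of 20 that fell, and 10 fell adjusted over the list alone. The arterial list had a median of -0.39 (limma's camera adjusted p = 3.5e-09, and adjusted p = 0.0304 with an estimated correlation). Of 14 endocardial genes 2 fell, the cadherin gene Cdh11 with a log2 fold change of -1.67 ± 0.28 and the transcription factor gene Gata5 with -2.60 ± 0.47 (SE, edgeR adjusted p = 0.0163 and 0.0223). Adjusted over the list alone, 5 fell and 1 rose. The endocardium list had a median of -0.46 (camera adjusted p = 9.18e-05, but adjusted p = 0.259 with an estimated correlation). The Cdh11 call ended without replicate 1 of either group or tdTom- replicate 2 (adjusted p from 0.0517 to 0.0722), and the Gata5 call without any of 5 libraries, all but tdTom+ replicate 3 (0.0525 to 0.171), or with limma-voom (0.0637).

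**Figure D2:**
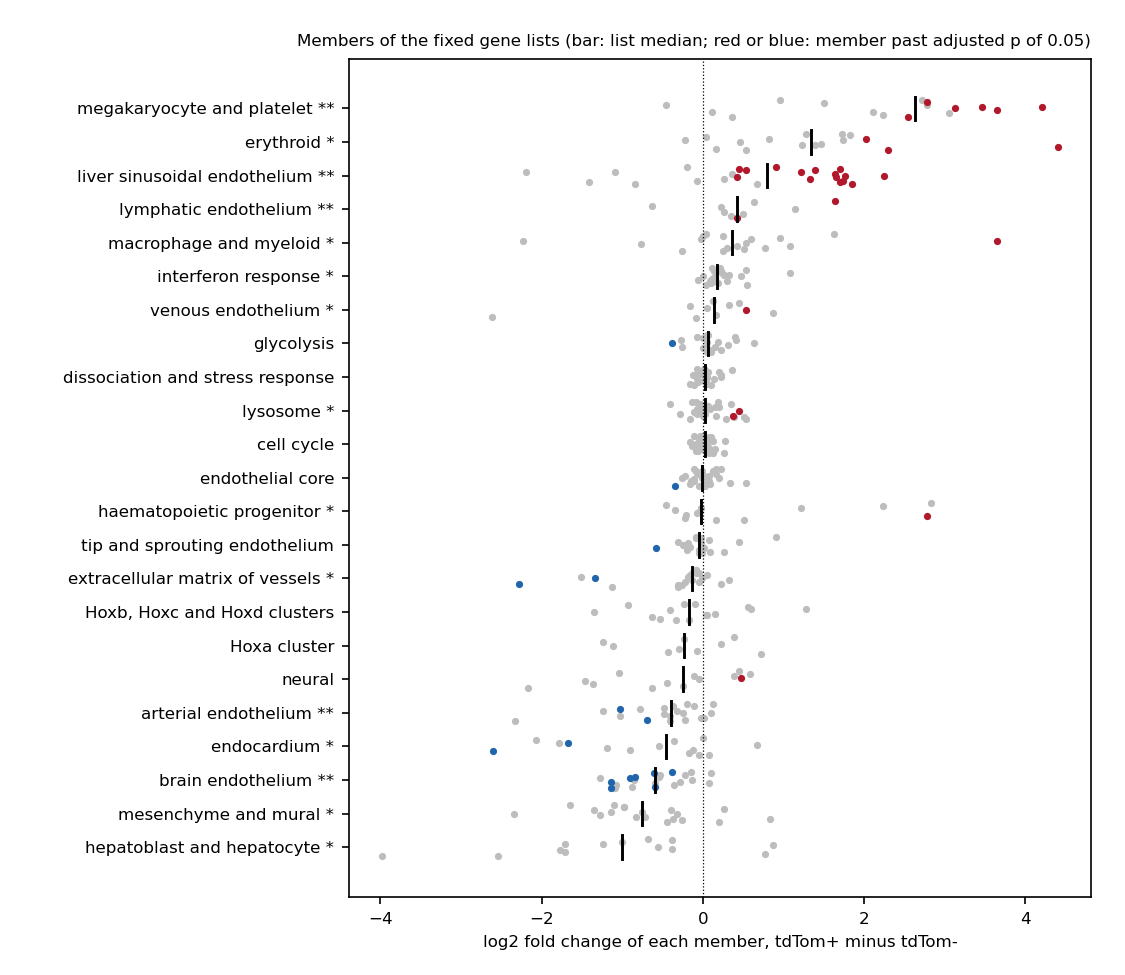
Log2 fold change (tdTom+ minus tdTom-) of each measured member of the 23 tested gene lists, with the list median as a black bar and members that rose or fell in red or blue. An asterisk marks a list called by camera with the preset correlation, such as endocardium at -0.46, and a further asterisk a list also called with an estimated correlation, such as liver sinusoidal endothelium at 0.79.

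Megakaryocyte and platelet genes were higher in tdTom+ cells. Of 16 measured megakaryocyte and platelet genes 6 rose and 0 fell; adjusted over the list alone, 12 rose. Itga2b, the platelet integrin subunit gene, rose from 15.0 ± 0.692 to 103 ± 35.7 CPM (SD, n = 3) and Plek, which encodes a platelet kinase substrate, by 2.55 ± 0.26 on the log2 scale (SE, edgeR adjusted p = 0.000873). The list median was 2.63 (limma's camera adjusted p = 2.57e-34, and adjusted p = 0.0304 with an estimated correlation). Of 16 erythroid genes 3 rose, the transcription factor genes Gata1, Nfe2 and Klf1, and 9 rose adjusted over the list alone. The erythroid list had a median of 1.34 (camera adjusted p = 5.19e-11, but adjusted p = 0.129 with an estimated correlation). The embryonic globin genes, named after their values were seen, did not pass, with log2 fold changes of 0.04 ± 0.22 for Hbb-y, 0.47 ± 0.32 for Hba-x and 0.17 ± 0.35 for Hbb-bh1 (SE). The calls of Nfe2 and Klf1 ended without any of 5 libraries, all but tdTom+ replicate 3 (adjusted p from 0.0748 to 0.126 and from 0.0773 to 0.162) and with limma-voom (0.0637 and 0.11).

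The macrophage and myeloid list was called higher with 1 of 18 members rising, Pf4, which is also a platelet gene; adjusted over the list alone that count was again 1. Its median was 0.36 (limma's camera adjusted p = 0.0197, but adjusted p = 0.18 with an estimated correlation). The haematopoietic progenitor list was called higher with 1 of 13 members rising, Itga2b, and with 3 rising and 1 falling adjusted over the list alone. The list's median was -0.02 and its mean 0.64, so that median and test differed in sign (camera adjusted p = 0.0159, but adjusted p = 0.259 with an estimated correlation). With members shared between lists left out, an alternative chosen after the data were seen, both calls ended (adjusted p = 0.297 and 0.992). The macrophage call also ended without tdTom+ replicate 2 (adjusted p = 0.188), tdTom+ replicate 3 (0.0747) or tdTom- replicate 2 (0.1), with limma-voom (0.098) and with fry (0.102). The haematopoietic progenitor call ended without tdTom+ replicate 1 (adjusted p = 0.0643), with the stricter filter (0.259), limma-voom (0.28) and fry (0.117), and with the genes of 4 other cell types removed (0.976).

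Of the vessel matrix genes, Eln and Fbln5 were lower in tdTom+ cells. Eln, which encodes elastin (chromosome 5, 134702595 to 134747368), fell from 314 ± 83.8 to 64.5 ± 10.1 CPM (SD, n = 3), a log2 fold change of -2.29 ± 0.19 (SE, edgeR adjusted p = 0.000292). Fbln5, which encodes an elastic fibre protein, had a log2 fold change of -1.34 ± 0.24 (SE, edgeR adjusted p = 0.0246). These were the 2 of 22 measured members of the vessel matrix list that fell, and 5 fell adjusted over the list alone. The matrix list had a median of -0.13 (limma's camera adjusted p = 2.15e-06, but adjusted p = 0.259 with an estimated correlation). The Fbln5 call ended without any of 5 libraries, all but tdTom- replicate 3 (adjusted p from 0.0666 to 0.134), and with either other filter or limma-voom.

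Markers of 2 non-endothelial tissues, mesenchyme and liver parenchyma, were called lower as lists without a single member passing, over all genes or adjusted over the list alone. The mesenchyme and mural list had a median of -0.75 over 19 genes (limma's camera adjusted p = 0.000617, but adjusted p = 0.335 with an estimated correlation). In it, Lum had a log2 fold change of -1.28 ± 0.34 and Twist2 one of -2.35 ± 1.03 (SE). The hepatoblast and hepatocyte list had a median of -1.002 over 13 genes (camera adjusted p = 0.00983, but adjusted p = 0.335 with an estimated correlation), and lost its call without tdTom+ replicate 1 (adjusted p = 0.0558) or tdTom- replicate 3 (0.148, with a median of -0.22). Trf in this list had a log2 fold change of -0.38 ± 0.13 and Dlk1 one of -1.70 ± 0.48 (SE). With the replicate block, Dlk1 and Lum passed (edgeR adjusted p = 0.000865 and 0.0213). Dlk1 also passed without tdTom- replicate 2 (adjusted p = 0.0175), and Lum with DESeq2 (0.0139).

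The lysosome and interferon response lists were called higher with the preset correlation only. Of 29 lysosomal genes 2 rose, the protease genes Ctsl and Ctsd, by 0.45 ± 0.08 and 0.38 ± 0.07 on the log2 scale (SE, edgeR adjusted p = 0.0163 and 0.0271), and 3 rose adjusted over the list alone. The lysosome list had a median of 0.03 (limma's camera adjusted p = 0.0462, but adjusted p = 0.361 with an estimated correlation). That call ended without tdTom+ replicate 1 (0.0558), tdTom+ replicate 2 (0.23, with a median of -0.03) or tdTom- replicate 2 (0.0972), and with library size only (0.0557), the stricter filter (0.107) or fry (0.136). Leaving out Ctsl, the member shared with another list, ended it as well (0.156). The Ctsl call ended without tdTom+ replicate 2 or any tdTom- replicate (adjusted p from 0.0523 to 0.0899), and the Ctsd call without replicate 1 or 2 of either group (0.0755 to 0.171). None of the 22 interferon response genes passed in edgeR, while 21 had positive log2 fold changes and 3 rose adjusted over the list alone. Lgals3bp and Mx1 had log2 fold changes of 0.55 ± 0.13 and 1.09 ± 0.29 (SE), and with the replicate block Lgals3bp passed (edgeR adjusted p = 0.0225). It also passed with both other filters (0.0328 and 0.047), DESeq2 (0.00244) and limma-voom (0.0496), and Mx1 with DESeq2 (0.0357). The interferon list had a median of 0.18 (camera adjusted p = 5.12e-06, but adjusted p = 0.32 with an estimated correlation).

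General endothelial genes showed no shared direction between the fractions as a list. Of 30 core endothelial genes 1 fell, Cd34, which encodes a surface sialomucin, with a log2 fold change of -0.35 ± 0.06 (SE, edgeR adjusted p = 0.0254). That call ended without any of 5 libraries, all but tdTom+ replicate 2 (adjusted p from 0.0635 to 0.121). The core list had a median of -0.01 and a mean of 0.01, which differ in sign (limma's camera adjusted p = 0.911), and 1 fell adjusted over the list alone. Of 20 tip and sprouting genes 1 fell, the growth factor gene Pdgfb, with a log2 fold change of -0.58 ± 0.12 (SE, edgeR adjusted p = 0.0366) and a call that ended when any library was left out (0.0503 to 0.173). The tip list had a median of -0.05 (camera adjusted p = 0.388), with 1 rising and 2 falling adjusted over the list alone. Camera looks for a shared direction, so members moving both ways can cancel. The mixed form of fry counts changes either way, without comparison to other genes. It gave an unadjusted p of 0.000493 for the core list and 1.8e-06 for the tip list.

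The homeobox lists were not called. None of the 9 measured Hoxa genes passed, over all genes or adjusted over the list alone, and the list had a median of -0.23 (limma's camera adjusted p = 0.388). Hoxa10 and Hoxa7 had log2 fold changes of -1.23 ± 0.39 and -1.12 ± 0.37 (SE, edgeR adjusted p = 0.207 and 0.235). None of the 15 measured genes of the Hoxb, Hoxc and Hoxd clusters passed in edgeR either way, with a median of -0.17 (camera adjusted p = 0.388). Hoxb7 had a log2 fold change of -0.63 ± 0.25 and Hoxb9 one of -0.93 ± 0.45 (SE). The groups did not overlap in any of these 4 genes, but they were picked for the smallest p in their lists. Over all tested genes 17.2% did not overlap. Hoxa7 was at 3.86 ± 0.882 CPM in tdTom+ and 8.39 ± 0.900 CPM in tdTom- cells (SD, n = 3). None of the 4 passed after adjustment over 13142 genes.

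Genes of division, stress and sugar metabolism were not called as lists. None of the 30 cell cycle genes and none of the 22 dissociation and stress genes passed in edgeR, over all genes or adjusted over the list alone, and both medians were 0.03 (limma's camera adjusted p = 0.388 for each). Mki67 and Cenpe had log2 fold changes of 0.26 ± 0.09 and 0.28 ± 0.11, and Myc and Socs3 of 0.23 ± 0.08 and 0.20 ± 0.11 (SE). Of 20 glycolysis genes 1 fell, Slc2a1, and adjusted over the list alone 1 rose and 1 fell (median 0.06, camera adjusted p = 0.257). Of 13 neural genes 1 rose, Gap43, which encodes a growth cone protein, with a log2 fold change of 0.47 ± 0.09 (SE, edgeR adjusted p = 0.0242). Its call ended without any of 5 libraries, all but tdTom+ replicate 2 (adjusted p from 0.0501 to 0.15). Adjusted over the list alone, 1 neural gene rose and 3 fell, and the list had a median of -0.24 (camera adjusted p = 0.0842). It was called lower without tdTom+ replicate 2 (adjusted p = 0.0353), without tdTom- replicate 3 (0.0251) and without the low-count filter (0.0486).

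**Figure D3:**
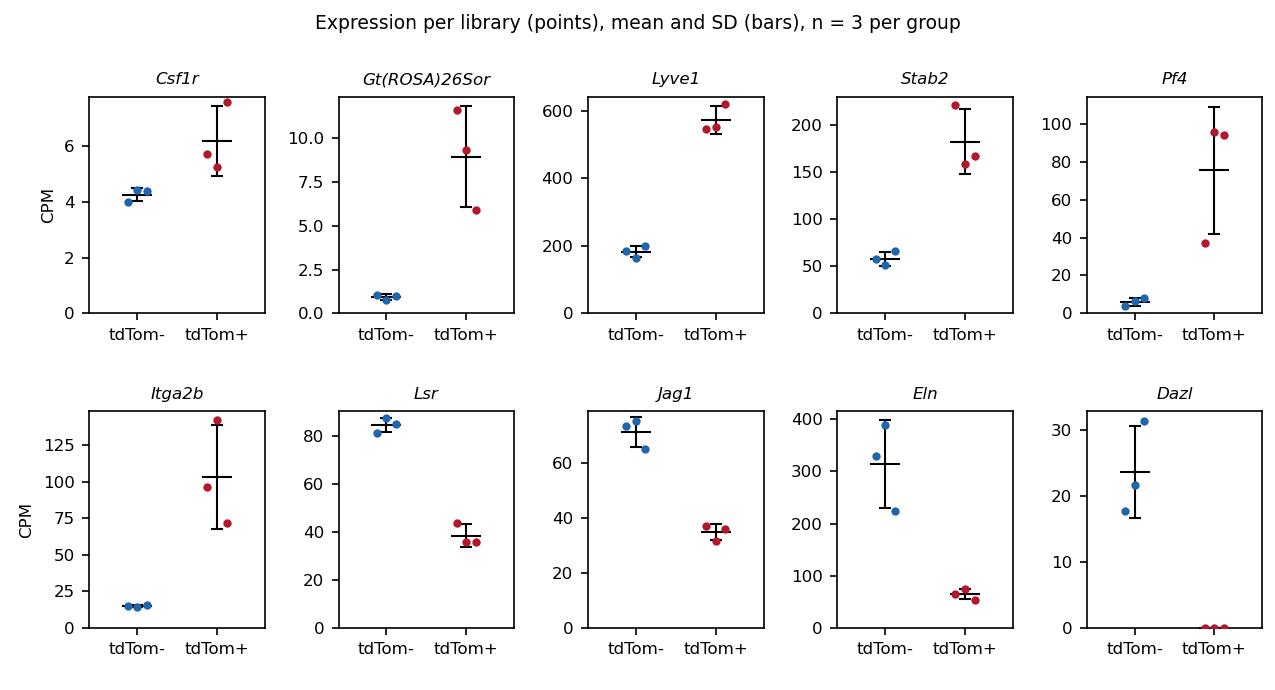
CPM (vertical axis, linear, starting at 0) of 10 genes in each of the 3 tdTom- libraries (blue) and 3 tdTom+ libraries (red). Bars are group means and whiskers 1 SD, and Csf1r lies at 6.16 CPM in tdTom+ against 4.25 in tdTom-, Lyve1 at 572 against 183, and Dazl at 0 against 23.5.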

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

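The removal of germ cell genes and the lists without shared members were tested only after the data were seen. Counts of genes stayed within 1.5 times of 101 higher and 107 lower under both other normalizations, both other filters, limma-voom and either removal of other cell types' genes, at 69 to 113 higher and 80 to 144 lower. DESeq2 called 217 higher and 267 lower, the authors' deposited comparison held 211 and 291, and the replicate block 167 lower, with 128 higher. Leaving out 1 library gave 37 to 97 higher and 25 to 92 lower genes, where 2 libraries in a group leave less power. The cause of the larger DESeq2 counts was not tested. Among the 9 lists higher and 6 lower, an estimated correlation left 3 and 2, and fry 5 and 2. Removing the genes of 4 other cell types left 5 higher lists, since 3 of the 9 are then not tested and the haematopoietic progenitor list lost its call, and leaving out shared members left 5 higher. Leaving out 1 library gave 6 to 9 higher and 5 to 7 lower lists. No named gene called in edgeR or in an alternative changed direction, and the authors' deposited comparison held 0 calls opposite to those here. Of 48 called named genes, 17 passed in all alternatives and 22 with any 1 library left out. Of 21 uncalled ones, 5 passed in some alternative. Some of these genes were chosen after their values were seen. They are Gt(ROSA)26Sor, Pou5f1, Dppa4, Ddx4, Stab2, Foxf1 and Fendrr among the called, and Hbb-y, Hba-x, Hbb-bh1 and Gpihbp1 among the uncalled. The replicate block changed no other call among the named genes or lists than those of Dlk1, Lum and Lgals3bp. Of 15 called lists, 5 kept their call in all alternatives (liver sinusoidal, lymphatic, arterial, brain, and megakaryocyte and platelet). Liver sinusoidal medians ran from 0.71 to 1.27 and brain medians from -0.72 to -0.58. At this depth a level under that of 3 counts, 0.255 to 0.336 CPM, cannot be told from 0.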

Other observations

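Some elastic fibre genes other than elastin were also lower in tdTom+ cells. In a list of 19 measured elastic fibre genes, 7 fell and 0 rose, with Eln and Fbln5 among the 7. The list was assembled after the fall of Eln and Fbln5 was seen, so no test of it is given. Mfap2, a microfibril gene, fell from 219 ± 15.7 to 119 ± 14.2 CPM (SD, n = 3), the TGF-beta binding protein gene Ltbp4 from 168 ± 31.4 to 92.1 ± 6.47 CPM (SD, n = 3), and Fbln2 from 173 ± 46.2 to 43.2 ± 20.7 CPM (SD, n = 3). Fbn2 and Efemp2 did not pass in edgeR, with log2 fold changes of -0.01 ± 0.13 and 0.06 ± 0.14 (SE). The list median was -1.15. Several of these genes are also expressed by mesenchyme, and the mesenchyme and mural list had a median of -0.75, with 16 of 19 members negative and 0 passing (limma's camera adjusted p = 0.000617, but adjusted p = 0.335 with an estimated correlation).

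Some genes of Wnt ligands and their Frizzled receptors were lower as well. Of 18 measured genes 5 fell and 0 rose, in a list assembled after the fall of Wnt4 and Wnt9b was seen, so no test of it is given. Beside Wnt4 and Wnt9b these were Wnt11 at -1.55 ± 0.26, Fzd1 at -1.59 ± 0.31 and Fzd6 at -0.74 ± 0.13 on the log2 scale (SE, edgeR adjusted p = 0.017, 0.0299 and 0.0213). Fzd4, a receptor of brain endothelium, was at 91.3 ± 8.71 CPM in tdTom+ and 85.3 ± 11.4 CPM in tdTom- cells (SD, n = 3). The list median was -0.58.

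Of the tests that follow, those on globins, genes detected, hepatoblasts, macrophages and the share of liver cells were chosen after the result was seen. Bounds are the estimate plus or minus 2 SE, and those of list medians rest on the spread between genes, not between libraries. Megakaryocyte and platelet genes were higher in tdTom+ cells, as was the erythroid list with 3 of 16 members passing (limma's camera adjusted p = 5.19e-11, but adjusted p = 0.129 with an estimated correlation). Platelets and megakaryocytes carry PECAM1, for which the cells were sorted, while megakaryocytes also carry CD45, which the gate removed. The summed embryonic globins, the most abundant transcripts of primitive red cells, had a log2 fold change of 0.11 ± 0.23 (SE). The upper bound of 0.58 lies below the erythroid median of 1.34, which argues against carried-over primitive red cells. Other erythroid cells are not covered by this sum, and their carry-over was not tested. Carry-over of megakaryocytes or platelets may account for the pattern: a second list of 22 megakaryocyte genes, 20 of them measured, none in a fixed list and not looked at beforehand, had a median of 0.59 ± 0.18 (SE), with 19 positive and 0 passing alone (limma's camera p = 2.26e-10, and p = 0.00862 with an estimated correlation). Expression of these genes by the tdTom+ endothelial cells themselves would raise the second list too, so the list does not tell it from carry-over. Such expression stays open and was not tested.

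Germ cell genes were lower in tdTom+ cells, in a list of 14 chosen because they fell, with a median of -8.87, or -6.01 with genes at 0 counts set to their bound. Fewer genes were detected in tdTom+ libraries. The 5792 other genes with the same range of tdTom- counts (43 to 1028) had a median log2 fold change of -0.0416. Its lower bound was -0.0558, but normalization centres the genes near 0, so this median cannot decide on lost detection. Of these 5792 genes, 9 (0.155%) had 0 counts in all tdTom+ libraries, so a complete loss at such counts was rare outside the germ cell lists. Germ cells in the tdTom- fraction may be the source: in a second list of 25 genes, written before any of them was looked at, the 11 that passed the low-count filter, 9 of them under 1 CPM in tdTom+ cells, had Dazl and Dppa3 lower, 0 higher and a median of -2.75 ± 0.84 (SE). The 9 measured members other than Dazl and Dppa3, all negative and 0 passing, had a median of -2.32 ± 0.66 (SE, limma's camera p = 1.17e-07 over these genes, and p = 0.0258 with an estimated correlation). Genes so low in tdTom+ cells pass the filter mainly through their tdTom- counts, so the filter favoured negative signs and these p-values are not independent support. Of the 14 that the filter left out, 12 had fewer and 1 had more counts in tdTom+ libraries. These 14 had 21 counts in all tdTom+ and 408 in all tdTom- libraries. Primordial germ cells carry PECAM1, but also KIT, which the gate should have removed, and how they would have passed was not tested. Kit RNA was present in both fractions, at 119 ± 6.10 CPM in tdTom- and 86.7 ± 5.99 CPM in tdTom+ cells (SD, n = 3). That difference missed the threshold in the main fit (edgeR adjusted p = 0.0581). Whether gonad or mesonephros cells came along cannot be told. Those 12 genes had a median of -0.30 ± 0.49 (SE), with 0 passing, and a range of 2 SE around it spans both no change and a 2-fold fall.

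Liver sinusoidal genes were higher in tdTom+ cells. Hepatoblast carry-over is argued against by the hepatoblast median, whose upper bound of -0.28 lies below the liver sinusoidal median of 0.79, although without tdTom- replicate 3 the hepatoblast median moved from -1.002 to -0.22 and its upper bound to 0.58, against a liver sinusoidal median of 0.82. Macrophages are argued against by C1qa, C1qb, C1qc, Tyrobp, Fcer1g and Lyz2, whose summed gain of 12.1 ± 3.04 CPM (SE) has an upper bound of 18.2 CPM, while Mrc1 gained 63.2 and Lyve1 389 CPM. A larger share of liver endothelial cells in the tdTom+ fraction is a candidate explanation: the brain and endocardium medians were -0.60 and -0.46, although the endocardium call was lost with an estimated correlation (adjusted p = 0.259). A change of these genes within cells of one organ stays open, since whole embryos were sorted.

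The 6 libraries can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. The real division gave 208 genes, the only one of the 10 (1 of 10) to reach that number, and the highest of the other splits gave 0. For gene lists the real division gave 15 and the highest of the other splits 8, again 1 of 10. With the preset correlation, camera thus called 2 to 8 lists in divisions that mix the groups. In such divisions the real difference lies partly within the sides, which lowers gene calls, and partly between them. Their counts are therefore not rates of false calls. Among the 3 other divisions that part all same-numbered libraries, as the real one does, 0 genes and 2 to 6 lists were called, and the others each part 1 such pair.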
